A study of Mus musculus with 2 samples.

How the data were processed

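H3K4me3 ChIP-seq was done on midbrain tissue of mouse embryos at day 13.5, with 2 biological replicates in 1 group, per the labels. Both replicates carry the same donor entry in the labels, for strain B6NCrl, with pooled sexes, so whether they came from separate litters is not given in the sources used here. The labels list a possible control experiment, which was not used here.

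The authors deposited 4 peak lists in narrowPeak format on build mm10. Per the labels and the description files deposited beside them, the lists of replicates 1 and 2 were each derived from that replicate's filtered alignment and 1 further file, and the pooled list from both alignments. The replicated list was derived by the authors from both replicates' lists and the pooled list. The aligner, the peak caller, its thresholds and the rule for a replicated peak are not given in the sources used here. The deposited columns give each peak a display score, an enrichment signal, the −log10 of its p-value and the −log10 of its q-value. The score was not used. The signal is the authors' own value for a peak. The plan made before the data were examined called it a fold enrichment, but no source says that it is a fold over control. It is therefore called signal and used only within 1 list, to describe, rank or match peaks and, in tests chosen after the data were seen, to compare gene lists. The smallest deposited −log10 p-value in each list was between 2.00 and 2.15, so weak peaks are included. In the replicated list 57 of 24227 peaks had a −log10 q-value under 2, against 2944 of 30496 in replicate 1 and 1930 of 29366 in replicate 2. No read numbers are given, so depth is unknown and differences in depth between the replicates could shift which weak peaks were called.

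Coordinates were checked against the GRCm38 genome: no peak reached past the end of a chromosome, and 12 replicated peaks lay on scaffolds outside the chromosomes. Genes and TSSs were taken from the GENCODE annotation of the same build, with genes of the mitochondrial genome left out. A protein-coding gene was called marked where a peak reached within 1000 bp of the TSS of any of its protein-coding transcripts. Peaks were joined into domains across gaps of at most 500 bp, and a gene's domain was the widest that reached within 1000 bp of 1 of its TSSs. Genes that share a domain each carry its width. The CpG ratio is the observed over the expected number of CpG dinucleotides in the TSS window, the highest over a gene's TSSs. Overlaps were counted with bedtools 2.31.1 at a minimum of 1 bp. The rest was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Values from the replicates' own lists are given as mean ± SD with n = 2.

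Before the data were examined, 19 gene lists were fixed, of which 1, olfactory receptors, was defined by its symbols and held 1134 genes. All members of the other lists were found in the annotation except 1 of 18 erythroid genes, Ahsp. Marking of each list was compared with all other protein-coding genes by Fisher's exact test (two-sided). Median domain widths were compared with all marked genes by a permutation test of 100000 random lists of equal size (two-sided), for lists with at least 10 marked members. Membership in the top 5% of widths was compared by Fisher's exact test (two-sided). In each family p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Many list members are neighbours or relatives, so genes are not independent, which such tests do not model. Per-gene tests between conditions were not possible, as there is 1 group.

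The list tests were tried on simulated data with 100 lists of 20 genes each. Lists with widths multiplied by 1.5 were called in 93 of 100 cases, and unchanged lists in 8 of 100. For marking, lists with 30.0% of genes marked were called in 88 of 100 cases, and unchanged lists in 4 of 100. For the broadest domains, lists with widths multiplied by 2 were called in 98 of 100 cases, and unchanged lists in 2 of 100. These calls used unadjusted p-values.

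Genes named in the text were chosen by a rule fixed before the data were examined. It took the 15 widest domains and the 10 genes with the highest signal. From each list it took the 3 marked members with the widest domains and up to 3 unmarked members in alphabetical order. It took the 3 genes marked in each replicate only with the highest signal, and the genes nearest the 5 strongest peaks over 5000 bp from any TSS. Predicted genes with Gm or Rik names were left out of the last groups and of the highest signals. Cd68, Nfe2, En1, Pax7, Wnt1, Fgf8, Nkx2-2, Slc6a3, Slc18a2 and the globin genes were named after their values were seen.

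Alternatives covered the peak list (pooled, or either replicate alone), thresholds of 2 on −log10 q and 5 on −log10 p, TSS windows of 500 and 2500 bp and the most upstream TSS only. They also covered gaps of 0, 1000 and 3000 bp, the top 2% and 10% of widths, distances of 2500 and 10000 bp, other overlap rules and 10000 random lists matched on CpG ratio. Counting each domain once was added after the data were seen.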

Results

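H3K4me3, the trimethylated form of lysine 4 on histone H3, was mapped by ChIP-seq in midbrain of mouse embryos at day 13.5. The mark lies at transcription start sites (TSSs) of genes that are transcribed or held ready for transcription. At this age the midbrain holds dividing neural progenitors and newly formed neurons. The series had 1 group of 2 biological replicates from strain B6NCrl, with male and female tissue pooled. Its peak lists, in mouse genome build mm10 (GRCm38), numbered 4: 1 for each replicate, 1 for both replicates pooled, and the replicated list that the authors derived from the others. The lists give no read numbers, so the depth of each library is unknown. With 1 group, the comparisons were between the replicates and between classes of genes within the lists. Tests of gene lists compare genes within these libraries, since genes are not replicates of the tissue.

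In the replicated list, 14283 of 21930 protein-coding genes (65.1%) carried a peak within 1000 bp of a TSS and are called marked here. The replicates' own lists marked 14322.5 ± 54.4 genes (SD, n = 2), and 14219 genes were marked in both. Among genes whose TSS window had an observed to expected CpG ratio over 0.6, 99.3% of 8234 were marked. Of the 13619 genes at or below that ratio, 44.8% were marked. By enrichment signal, the authors' own value per peak, Eif3b, a translation initiation factor subunit, was highest at 80.8, and Eef2, a translation elongation factor, had 79.6. Sox4, a transcription factor of newly formed neurons, stood at 80.5, as did Atp13a1 and Zfp866, which share 1 peak. Msl1 (79.9), Dpm1 and Mocs3 (both 79.7, at a shared peak), Rab14 (79.6) and Pgs1 (79.4) completed the 10 highest. The order differed between the replicates: Eif3b had 53.0 in replicate 2's own list, below Sox4 at 69.6, and Atp13a1 and Zfp866 had 52.4 in replicate 1's.

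Genes that pattern the midbrain and isthmus, the boundary with the hindbrain, were marked without exception in the replicated list, 20 of 20. They include Otx2, En1, Pax7, Wnt1 and Fgf8. The lists of neural progenitor genes, genes of neurons in general, telencephalon genes, and hindbrain and spinal cord genes were also marked at 20 of 20 each. For each of these 5 lists Fisher's exact test (two-sided) against all other protein-coding genes, of which 65.1% were marked, gave an adjusted p of 4.73e-04. The 20 housekeeping genes gave the same count and p. Of 23 genes of tectal, GABAergic and motor neurons, 22 were marked (adjusted exact p = 0.00225). The exception was Phox2b, a regulator of oculomotor and visceral motor neurons, although with a window of 2500 bp 100% of this list was marked. Against random lists matched on CpG ratio, of these 7 lists only general neuronal genes passed (adjusted permutation p = 0.0258). For the others, matched lists were marked at means of 92.1 to 98.8%, with the central 95% reaching 100%. A higher share could therefore not pass there, and the comparison does not settle whether CpG content accounts for their marking. Floor plate and dopaminergic genes were marked at 16 of 18, which did not pass (adjusted exact p = 0.0654). Unmarked there were Th, the rate-limiting enzyme of dopamine synthesis, and Aldh1a1, a retinaldehyde dehydrogenase of a subset of dopaminergic neurons. Their CpG ratios were low, at 0.190 and 0.187. Slc6a3, the dopamine transporter, was marked by a domain of 1060 bp, and Slc18a2, the vesicular monoamine transporter, by one of 1173 bp.

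Genes of other cell types divided into several classes. None of the 18 microglia and macrophage genes was marked in the replicated list (adjusted exact p = 5.45e-08), among them Aif1, C1qa and C1qb. One of them, Cd68, had a TSS peak in each replicate's own list, with widths of 575 and 211 bp. Erythroid genes were marked at 4 of 17 (adjusted exact p = 9.71e-04), namely Epor, Klf1, Gypa and Nfe2, while no globin gene of the list was. Hba-a1 and Hba-a2 are near-identical copies, and reads shared between them can be lost in mapping. Liver genes were marked at 2 of 18 (adjusted exact p = 2.07e-05). The 2 were Apoh and Vtn, and the Vtn domain shared no base with the gene itself. Germ line genes were marked at 4 of 18 (adjusted exact p = 4.73e-04), with Tdrd5 (1512 bp) and Dazl (907 bp) widest and Brdt, Ddx4 and Gdf9 unmarked. Of 1134 olfactory receptor genes 3 were marked (0.265%), Olfr94, Olfr658 and Olfr1033, against 68.7% of all other genes, the smallest p of the 19 lists. Matched on CpG ratio, the erythroid (adjusted permutation p = 1.00) and liver lists (adjusted permutation p = 0.544) no longer passed. The germ line and olfactory receptor lists still passed (adjusted permutation p = 0.00127 each), and the microglia list passed narrowly (adjusted permutation p = 0.0469). Of the liver genes 22.2% were marked with a window of 2500 bp and 5.56% with 500 bp.

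The remaining lists did not pass Fisher's exact test. Pericyte, meningeal and mesenchymal genes were marked at 17 of 20 (adjusted exact p = 0.123), but passed against lists matched on CpG ratio (85.0% against 67.3%, adjusted permutation p = 0.0258). Foxf2, Prrx1 and Foxc1, transcription factors of mesenchyme, had the widest domains there, at 6127, 4199 and 4160 bp, and the matrix genes Col3a1, Dcn and Lum were unmarked. Endothelial genes were marked at 10 of 18 (adjusted exact p = 0.513), with Kdr, a VEGF receptor, at 3223 bp, Slc2a1 at 3104 bp and Mfsd2a at 3089 bp. Unmarked endothelial genes included Cdh5, Emcn and Foxq1. In the oligodendrocyte lineage 10 of 16 were marked (adjusted exact p = 0.843). Olig2 (5043 bp), Pdgfra (4430 bp) and Nkx6-2 (4022 bp), all used by precursors, were widest, while Gpr17 and the myelin genes Mag and Mobp were unmarked. Astrocyte genes were marked at 10 of 15 (adjusted exact p = 1.00). Slc1a2 (6063 bp), Fgfr3 (5670 bp) and Gja1 (3170 bp) led that list. Agt, Aqp4 and Gfap were unmarked, although Aqp4 had a domain of 202 bp in replicate 1's own list. Skeletal and heart muscle genes were marked at 9 of 20 (adjusted exact p = 0.0871). Myod1 (1766 bp), Hand2 (1661 bp) and Tbx20 (1274 bp), all transcription factors, were widest, and Acta1, Actc1 and Ckm were unmarked. The unmarked genes named in this paragraph had CpG ratios of 0.154 to 0.294 and the marked ones 0.503 to 0.856. These splits can therefore not be told apart from CpG content. Without joining of peaks Foxf2 had 2831 bp and Pdgfra 2507 bp, and with joining across 3000 bp Olig2 had 12818 bp, Foxc1 11598 bp, Tbx20 11500 bp, Pdgfra 8891 bp, Prrx1 6826 bp, Mfsd2a 6690 bp, Nkx6-2 6278 bp and Slc2a1 5876 bp. In replicate 2's own list 35.0% of the muscle genes were marked, and that passed (adjusted exact p = 0.0117), as it did with a 500 bp window and with the most upstream TSS only.

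Hox genes, which set position along the hindbrain and trunk and are not used in the midbrain, were marked at 22 of 39 (adjusted exact p = 0.371). Hoxa1, Hoxc13 and Hoxd8 had the widest of these domains, at 1590, 1468 and 1465 bp, although Hoxc13 had 735 bp without joining of peaks. In the replicates' own lists Hoxa1 had 1128 ± 26.9 bp, below Hoxc13 at 1386 ± 198 bp and Hoxd8 at 1372 ± 225 bp (SD, n = 2). Hoxa10, Hoxa11 and Hoxa3 were among the unmarked, although Hoxa10 had a domain of 333 bp in replicate 1's own list. In the pooled list 79.5% of Hox genes were marked, above other genes (adjusted exact p = 0.122). Against a mean of 93.8% in random lists matched on CpG ratio, the 56.4% of Hox genes passed as lower (adjusted permutation p = 0.00127).

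**Figure D1:**
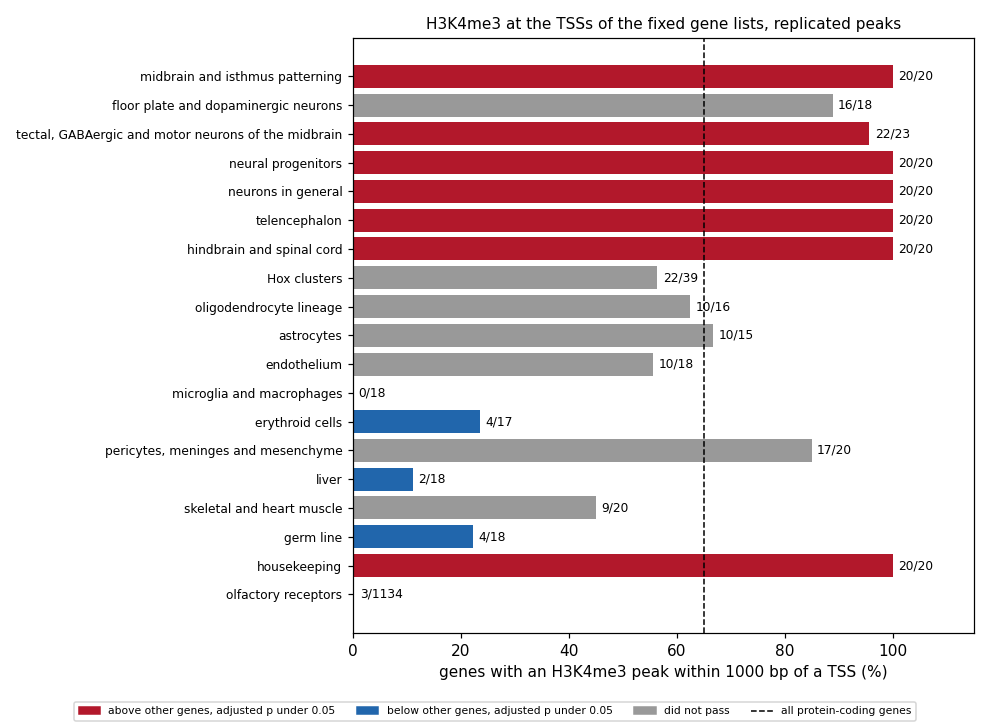
Percent of the genes of each fixed list (rows) with a replicated H3K4me3 peak within 1000 bp of a TSS (horizontal axis); numbers beside the bars are marked genes over genes in the list. Red bars passed Fisher's exact test above other genes and blue bars below them, as did the microglia (0 of 18) and olfactory receptor (3 of 1134) lists whose bars are too short to see; the dashed line is the 65.1% of all protein-coding genes.

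Genes of several neural lists had wider H3K4me3 domains than other marked genes. A gene's domain was the widest run of peaks at its TSSs, joined across gaps of at most 500 bp, and the median over marked genes was 2407 bp (quartiles 1745 and 3282 bp). Genes of tectal, GABAergic and motor neurons had a median of 9256 bp, neural progenitor genes 6755 bp, and midbrain and isthmus genes 6247 bp. General neuronal genes had a median of 5130 bp and telencephalon genes 4968 bp. In the permutation test (two-sided, 100000 random lists, adjusted over 13 lists) each of these 5 had an adjusted p of 4.33e-05, from an unadjusted p of 2.00e-05, the smallest these permutations can give. Hindbrain and spinal cord genes, with a median of 4210 bp, also passed (adjusted permutation p = 1.49e-04), as did housekeeping genes at 3454 bp (adjusted permutation p = 0.00692). Hox genes lay on the other side, with a median of 894 bp (adjusted permutation p = 4.33e-05). Against marked genes matched on signal, the Hox median lay within the central 95% of medians, 646 to 1127 bp. In replicate 1's own list the Hox median was 448 bp, below the matched range there of 528 to 1011 bp. It lay within that range in replicate 2's own list (703 bp, range 492 to 969 bp) and in the pooled list (566 bp, range 557 to 949 bp). With joining across 3000 bp the telencephalon median was 9870 bp.

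Within the midbrain and isthmus list, Meis2 had the widest domain, 21385 bp (21348 ± 14.8 bp, SD, n = 2, in the replicates' own lists). Otx2, the homeobox gene required for forebrain and midbrain, followed at 20418 bp (20110 ± 65.1 bp, SD, n = 2). Its domain on chromosome 14, positions 48654560 to 48674977, contained the whole gene, which the annotation places at 48657677 to 48673819 on the minus strand. Otx1 had 16345 bp (16320 ± 38.9 bp, SD, n = 2). In the neuronal list of the midbrain, Lhx1 (22176 bp), Gata3 (21755 bp) and Lhx5 (17465 bp) were widest, all transcription factors of GABAergic neurons or their precursors. Sox2 (18129 bp), Pax6 (16858 bp) and Zic1 (15913 bp) led the progenitor list. Myt1l (14152 bp), Scrt1 (8338 bp) and Tubb3 (8236 bp) led the neuronal list. The widest telencephalon domains were at Lhx2 (22071 bp), Emx2 (14444 bp) and Bcl11b (9793 bp), and the widest of the hindbrain list at Barhl2 (10829 bp), Prdm12 (8640 bp) and Gsx1 (6772 bp). In replicate 1's own list Emx2 had 8645 bp, below Bcl11b at 9175 bp. Without joining Barhl2 had 4030 bp, below Prdm12 and Gsx1, and Zic1 had 8091 bp, Pax6 10173 bp and Myt1l 8360 bp, whereas joining across 3000 bp gave Barhl2 23035 bp and Zic1 23898 bp.

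Floor plate and dopaminergic genes had a median of 2388 bp (adjusted permutation p = 0.975), although Nr4a2, Foxa1 and Lmx1a, transcription factors of this lineage, had 9124, 7863 and 7029 bp. Pericyte and mesenchymal genes (2421 bp, adjusted permutation p = 0.975), endothelial genes (2352 bp, adjusted permutation p = 0.975), oligodendrocyte genes (2227 bp, adjusted permutation p = 0.831) and astrocyte genes (2189 bp, adjusted permutation p = 0.829) did not pass either. The muscle (886 bp), erythroid (1166 bp), germ line (638 bp), liver (3034 bp) and olfactory receptor (439 bp) lists had fewer than 10 marked members and no test. With 10 marked members, muscle genes passed as narrower in replicate 1's own list (741 bp, adjusted permutation p = 8.00e-05), in the pooled list (875 bp) and with a 2500 bp window (1016 bp). Rpl13a (7502 bp), Polr2a (6290 bp) and Actb (5581 bp) were the widest housekeeping domains, and that of Rpl13a measured 3742 ± 78.5 bp (SD, n = 2) in the replicates' own lists and 2162 bp without joining. Without joining across gaps, the hindbrain median was 2961 bp and no longer passed (adjusted permutation p = 0.0610). With joining across 3000 bp, the floor plate and dopaminergic median was 4604 bp, with 16068 bp at Foxa1, above other genes, and passed (adjusted permutation p = 0.00101).

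**Figure D2:**
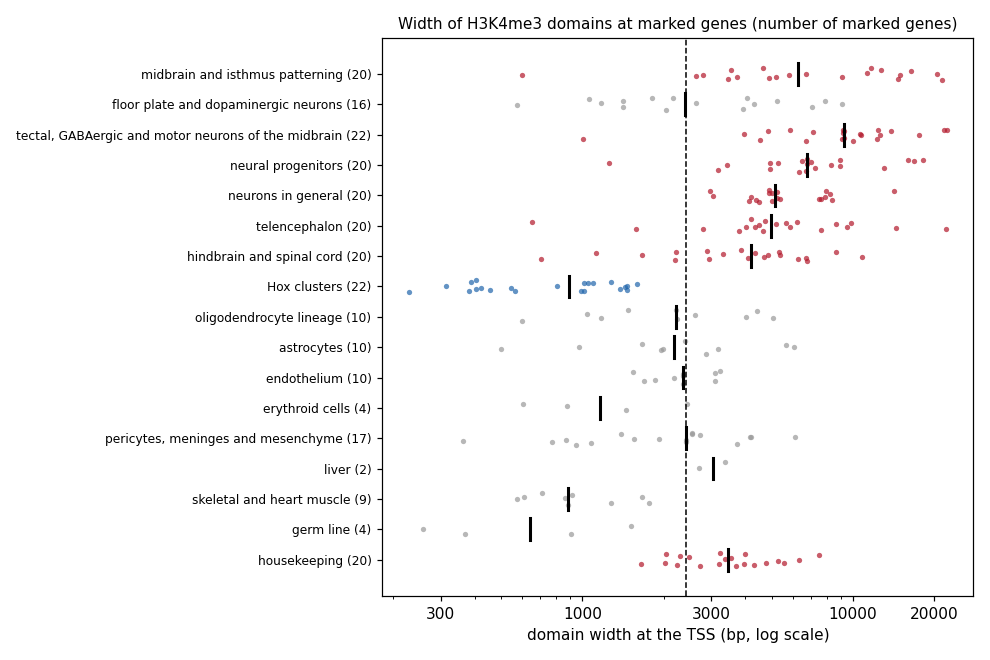
Width of the H3K4me3 domain at the TSS (horizontal axis, bp, log scale) of each marked gene (points) in each list (rows, with the number of marked genes); black bars are list medians and the dashed line is the median of all marked genes, 2407 bp. Lists in red passed the permutation test above other marked genes, the Hox clusters (blue, median 894 bp) passed below them, and lists in gray did not pass or were not tested.

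**Figure D3:**
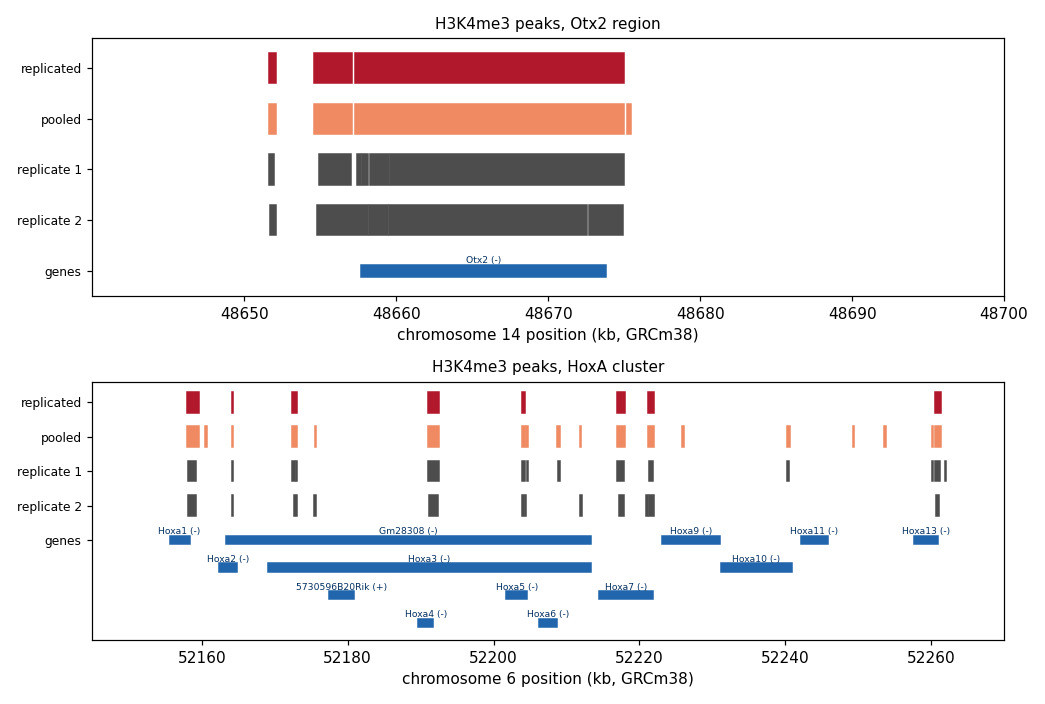
Peaks of the replicated, pooled, replicate 1 and replicate 2 lists (boxes) and protein-coding genes with their strand (blue) over position in kb, for the Otx2 region of chromosome 14 and the HoxA cluster of chromosome 6. In the replicated list the Otx2 gene lies within a domain of 20418 bp. The HoxA peaks are separate and short, with 1590 bp at Hoxa1 in that list.

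Across the genome, 92 marked genes had domains over 10000 bp. Pou3f3, a POU-domain factor of neural cells, was first at 30890 bp on chromosome 1, positions 42683892 to 42714781, a span that contains the whole gene. Its replicates measured 30720 and 22294 bp (26507 ± 5958 bp, SD, n = 2). Nr2f2 followed with 28474 bp (26258 ± 6.36 bp, SD, n = 2), then Ebf3 with 22467 bp (22462 ± 25.5 bp, SD, n = 2). Lhx1 shared its domain of 22176 bp, on chromosome 11, with the neighbouring Aatf. At Aatf the replicates gave 2231 and 21812 bp, since the run of peaks was broken between the genes in replicate 1. Gata3 shared its domain on chromosome 2 with 9230102O04Rik and 4930412O13Rik. Zfhx3 (21650 bp), Pou3f2 (19649 bp), Lhx9 (18697 bp), Mn1 (18037 bp) and Nfib (17869 bp) complete the 15 widest with Lhx2, Meis2, Otx2, Sox2 and Lhx5. Counting only each gene's most upstream TSS, Zfhx3 had 3414 bp, Nfib 1095 bp and Nr4a2 2141 bp, as their wide domains lie at internal TSSs. The order also rests on joining: without it Nr2f2 had 8819 bp, Pou3f3 18931 bp, Lhx1 12977 bp, Aatf 3550 bp, Sox2 11519 bp and Nfib 11395 bp, while Lhx2 and Meis2 kept their widths. In replicate 1's own list Nfib had 11314 bp.

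The top 5% of marked genes by width, 715 genes over 5449 bp, held members of 6 lists more often than chance. Tectal, GABAergic and motor neuron genes supplied 18 of 22 marked members (81.8%, against 4.89% of other marked genes, adjusted exact p = 3.46e-19, Fisher's exact test, two-sided). Progenitor genes supplied 14 of 20 (adjusted exact p = 1.45e-13), midbrain and isthmus genes 11 of 20 (adjusted exact p = 3.06e-09) and telencephalon genes 9 of 20 (adjusted exact p = 8.63e-07). General neuronal genes supplied 7 of 20 (adjusted exact p = 1.20e-04) and hindbrain and spinal cord genes 5 of 20 (adjusted exact p = 0.00769). Floor plate and dopaminergic genes, at 3 of 16 (adjusted exact p = 0.110), housekeeping genes, at 3 of 20 (adjusted exact p = 0.170), and astrocyte genes, at 2 of 10 (adjusted exact p = 0.173), did not pass. No Hox gene was among them. In the top 2% the hindbrain list no longer passed (2 members, adjusted exact p = 0.154). The floor plate and dopaminergic list passed without joining of peaks (4 members, adjusted exact p = 0.0209) and with joining across 3000 bp (5 members, adjusted exact p = 0.00256).

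The replicates' peak lists overlapped for most peaks and differed mainly in weak, narrow ones. Of 30496 peaks in replicate 1, 83.0% overlapped a replicate 2 peak by at least 1 bp, and 87.2% of the 29366 peaks in replicate 2 overlapped a replicate 1 peak. After shuffling along chromosomes 20 times, 2.81% of replicate 1 peaks overlapped on average (2.64 to 2.95%). Peaks without a partner had a median width of 232 bp in replicate 1 and 225 bp in replicate 2, against 1287 and 1241 bp for shared peaks. Their median signals were 2.98 and 3.03, against 19.8 and 18.7. Of the 24227 replicated peaks, all with coordinates identical to a pooled peak, 23017 overlapped both replicates' lists and 1210 did not. Across the 14219 genes marked in both replicates, domain widths had a Spearman's rho of 0.945, a correlation across genes, which are not independent replicates. The wider replicate exceeded the narrower by a median of 1.08 times, and 3.38% of genes differed by over 1.5 times.

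**Figure D4:**
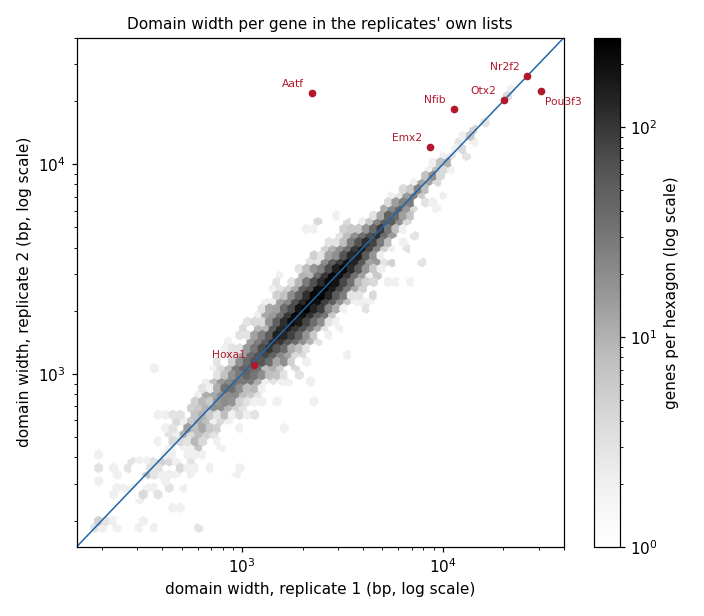
Domain width per gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both in bp on log scales, for the 14219 genes marked in both; hexagons are shaded by number of genes, the blue line marks equal widths, and red points are named genes. Nr2f2 and Otx2 lie on the line, while Pou3f3 (30720 and 22294 bp) and Aatf (2231 and 21812 bp) lie away from it.

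Genes marked in 1 replicate only numbered 142 for replicate 1 and 65 for replicate 2. Their median signals were 3.09 and 3.24, against 42.6 and 42.4 over all genes marked in those lists. The 3 with the highest signal in replicate 1 were Igflr1 (53.1), Gckr (45.8) and B3gnt4 (28.1). For all 3 the domain shared no base with the gene, and replicate 2 had a peak just beyond the window, 1058, 1003 and 1011 bp from the TSS. Such near misses were the minority: the other replicate had a peak within 2000 bp at 26 of the 142 genes and 16 of the 65. In replicate 2 they were Astl (26.7), Chrm1 (23.7) and Tsks (18.0), with the nearest replicate 1 peak 1252, 1045 and 1025 bp from a TSS. Where a peak was also required to be missing from the pooled list, 24 and 18 genes were left.

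Of the replicated peaks, 68.3% lay within 1000 bp of an annotated TSS, and these held 86.3% of the covered bases. A further 17.8% lay in gene bodies and 13.9% between genes. In the replicates' own lists the shares were 61.3% ± 1.17, 24.7% ± 0.770 and 14.0% ± 0.396 (SD, n = 2). Peaks over 5000 bp from every annotated TSS numbered 4299, with a median width of 641 bp and signal of 5.35, against 2028 bp and 42.1 for the 16547 peaks at TSSs. The strongest such peak, with a signal of 63.2, lay on chromosome 9, positions 32031157 to 32034759, in no annotated gene. It was 81377 bp from the nearest protein-coding TSS, that of Arhgap32. The next lay on chromosome 1, positions 171037661 to 171039227, 18741 bp from Fcgr4 (signal 60.2). A peak inside Ldb3 (chromosome 14, positions 34548325 to 34549854) had a signal of 57.6, at 38627 bp from that gene's nearest TSS. A peak inside Macrod1 (chromosome 19, positions 7163823 to 7166617) had 56.5 and was nearest to Otub1. The fifth lay 103445 bp from Dtna, on chromosome 18, positions 23309480 to 23311690 (signal 56.3). Against TSSs of protein-coding genes only, 6685 peaks were over 5000 bp away.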

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

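All tests in this part were chosen after the data were seen. Signal was present in genes that the comparisons above did not use. Long non-coding genes numbered 10155, of which 2624 (25.8%) had a replicated peak within 1000 bp of a TSS. At 742 of these genes the domain lay over 5000 bp from every protein-coding TSS, so it cannot be that of a neighbouring protein-coding promoter within that distance, and the median width there was 1207 bp. The widest of these domains at a gene without a Gm or Rik name, names chosen after their values were seen, was at Mir9-3hg, the host of a copy of the neural microRNA miR-9, on chromosome 7, positions 79495957 to 79512302. It spanned 16346 bp, and 14002 ± 461 bp (SD, n = 2) in the replicates' own lists. Mir124-2hg, the host of a copy of the neuronal microRNA miR-124, followed with 15957 bp (15924 ± 24.7 bp, SD, n = 2), and Mir124a-1hg had 9486 bp (9305 ± 75 bp, SD, n = 2). Malat1, an abundant nuclear RNA, had 9566 bp (9337 ± 182 bp, SD, n = 2) and the imprinted Peg13 had 6672 bp (6801 ± 214 bp, SD, n = 2).

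On 6 scaffolds that are not placed within the chromosomes there were 12 replicated peaks, with a highest signal of 41.4. Annotated genes on such scaffolds, if any, were not removed from the gene counts.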

How the results depend on the processing

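Over all alternatives of the main results, 641 values kept their direction and their side of the threshold, or stayed within 1.5 times a count or within the error of a share; of the rest, each counted once, 29 turned direction, whether or not they crossed the threshold, 8 lost and 8 gained it in the same direction, and 32 moved further. Counting each domain once was chosen after the data were seen; the other alternatives were planned. The cause was not tested for any change below unless stated. The higher widths of the 5 neural lists and the lower widths of Hox genes passed under every alternative to those comparisons, though the Hox median fell to 448 bp without replicate 2 and was not narrower than that of genes matched on signal in the replicated list (646 to 1127 bp); marked genes ranged from 13696 with the most upstream TSS only to 14499 with the 2500 bp window. Depth is not given, so its effect on weak peaks could not be measured. No paired analysis was possible because there is 1 group.

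Overlap of replicate 1 and of replicate 2 peaks was 77.5 and 82.3% when 50% of the peak was required, 71.9 and 74.7% when 50% of both was, 86.6 and 88.3% at −log10 q of at least 2, 90.0 and 91.3% at −log10 p of at least 5, 84.9 and 86.4% with equal numbers of top peaks, and 96.6 and 96.7% for the top 10000.

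Matched on CpG ratio, 2 lists were higher in marking instead of 7: general neuronal genes, as in the main comparison, and pericyte and mesenchymal genes, which passed only here. For the remaining lists of those 7, matched lists reached 100% marked, so a higher share could not pass there. Marking of midbrain and isthmus (100%, adjusted permutation p = 0.95), progenitor (100%, 0.372), telencephalon (100%, 0.544), hindbrain (100%, 1.00), housekeeping (100%, 1.00) and liver genes (11.1%, 0.544) no longer passed, nor did the tectal and erythroid lists below. That of Hox (56.4%, lower, 0.00127) and of pericyte and mesenchymal genes (85.0%, higher, 0.0258) passed. Direction turned, without passing, for tectal, GABAergic and motor neuron (95.7%; higher and passing in the main comparison), erythroid (23.5%; lower and passing there) and oligodendrocyte marking (62.5%) and for floor plate (2388 bp) and endothelial widths (2352 bp). The latter 2 widths also turned with each domain counted once (2388 and 2352 bp) and without joining (2388 and 2352 bp), as the comparison value fell below them.

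Without joining of peaks the hindbrain width no longer passed (2961 bp), the floor plate list gained the top 5% (4 members), and the oligodendrocyte (1 member) and pericyte lists (0 members) turned there. With a gap of 1000 bp, housekeeping genes gained the top 5% (4 members), and endothelial (2724 bp) and pericyte widths (2421 bp) and the oligodendrocyte top count (1 member) turned. With 3000 bp, endothelial (3416 bp), floor plate (4604 bp, then passing) and pericyte widths (2421 bp) turned, as did top counts of astrocyte (0 members), oligodendrocyte (2 members) and muscle genes (1 member), and the floor plate list gained the top 5% (5 members). In the top 2%, hindbrain genes no longer passed (2 members) and astrocyte (0) and pericyte genes (0) turned; in the top 10% pericyte genes turned (1 member).

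In the pooled list, Hox marking (79.5%), endothelial marking (66.7%), endothelial width (2492 bp) and pericyte width (2421 bp) turned without passing, and 2 lists were narrower instead of 1, Hox and muscle genes. At TSSs lay 58.4% of its peaks, in gene bodies 26.3% and between genes 15.3%. Without replicate 1 or 2, pericyte width was 1965 to 2076 bp, below other genes, muscle marking 35.0 to 50%, passing in replicate 2's own list alone, the number of narrower lists 1 to 2 (muscle genes too in replicate 1's own list), the share of peaks at TSSs 60.5 to 62.1% and in gene bodies 24.1 to 25.2%.

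With a 500 bp window 65.7% of peaks lay at TSSs, 19.9% in gene bodies and 14.4% between genes; with 2500 bp these were 75.9, 11.6 and 12.5%, by construction, and 2 lists were narrower, Hox and muscle genes. Muscle marking passed at 500 bp (35.0%, 0.0124) and with the most upstream TSS only (30.0%, 0.00686). Genes marked in 1 replicate only fell to 24 and 18 when absent from the pooled list, and 6685 peaks were over 5000 bp from protein-coding TSSs alone. Of the named gene widths, 46 of 76 moved by more than the replicates' SD without replicate 1, 41 of 77 without replicate 2, 41 of 79 without joining, 25 of 79 with a gap of 3000 bp and 7 of 77 with the most upstream TSS only. Genes marked in 1 replicate only are among these and have no such SD. With n = 2 the SD can be very small, as at Meis2 (14.8 bp for a domain of 21385 bp), so a move can be slight.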

Other observations

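In this part the tests of signal per list, of CpG content and joined peaks, of Hox paralog groups, of the caller's threshold, of signal in lists other than the replicated one, of all hindbrain explanations and of repeat-masked bases, and which neural lists form the first pattern, were settled only after the result was seen. Matching on CpG ratio and leaving peaks unjoined were planned as alternatives, but their use here as tests of an explanation was settled afterwards.

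Wide domains and strong peaks did not go together at several neural lists. The median TSS peak signal was 16.8 at telencephalon genes and 15.9 at hindbrain and spinal cord genes, against 49.2 at other marked genes (adjusted permutation p = 6.50e-05 each in a permutation test over 13 lists). At genes of tectal, GABAergic and motor neurons it was 23.4 (adjusted permutation p = 1.56e-04) and at midbrain and isthmus genes 31.1 (adjusted permutation p = 0.00454). Gata3 paired a domain of 21755 bp with a signal of 24.4, and Nkx2-2 one of 10684 bp with 8.70. General neuronal genes (55.7, adjusted permutation p = 0.159) and progenitor genes (48.5, adjusted permutation p = 0.892) did not pass, whereas housekeeping genes were higher at 60.1 (adjusted permutation p = 0.0133). Without wide domains, lower signals also passed at floor plate and dopaminergic genes (22.8, adjusted permutation p = 6.07e-04), and at Hox genes (4.19) and at pericyte and mesenchymal genes (13.4), with adjusted permutation p = 6.50e-05 each. Oligodendrocyte genes (21.0) and endothelial genes (20.9) passed at adjusted permutation p = 0.00364 each, and astrocyte genes (37.2, adjusted permutation p = 0.159) did not.

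The first pattern is the wide domains at 5 neural lists: midbrain and isthmus, tectal, GABAergic and motor neuron, progenitor, general neuronal and telencephalon genes. CpG ratio of the TSS window as the whole cause was argued against. That ratio was taken within 1000 bp of a TSS, so CpG content further out was not tested. The medians of 5 of the 5 lists lay above the central 95% of medians of lists matched on CpG ratio. The list medians also lay above the central 95% of medians of lists matched on number of annotated TSSs (5 of 5). Upper bounds there were 2950 to 3145 bp. In none of the 5 lists did the median number per gene exceed 2.00, the median over all marked genes. Both values argue against more TSSs per gene as the cause of these widths. Without joining of peaks the 5 lists still passed, with a highest adjusted permutation p of 4.33e-05. Their medians were lower, though: the tectal, GABAergic and motor neuron median fell from 9256 to 6420 bp. Progenitor genes then had 5954 bp, midbrain and isthmus genes 5507 bp, general neuronal genes 4524 bp and telencephalon genes 4514 bp. Part of the width at these lists may thus come from joined peaks. The hindbrain and spinal cord list, at 4210 bp, also exceeded the matched bounds, 3303 bp for CpG ratio and 2944 bp for number of TSSs. Its genes had a median of 1.00 annotated TSS, below the 2.00 over all marked genes. More TSSs per gene as the cause were thus argued against for this list too. Without joining, however, its median width was 2961 bp against 2320 bp for other genes (adjusted permutation p = 0.0610), so part of its width may also come from joined peaks. For the 5 lists a biological origin remains a hypothesis, found and tested on the same data and with no other tissue to compare.

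The second pattern is the narrow domains at Hox genes, with a median of 894 bp, but 448 bp over the 25 marked in replicate 1's own list and 566 bp over the 31 marked in the pooled list. Low signal of the peaks, whatever the gene, cannot be told apart. Medians of genes matched on signal ran from 646 to 1127 bp in the replicated list and from 557 to 949 bp in the pooled list. They ran from 492 to 969 bp in replicate 2's own list, where the Hox median was 703 bp. In replicate 1's own list they ran from 528 to 1011 bp, above the Hox median there. Closeness to the caller's threshold also stays open. Of the 22 marked Hox genes, 21 had a TSS peak in replicate 1's own list and 20 in replicate 2's. In each list 19 of them (86.4% of the 22) kept one of −log10 q of at least 2. However, that threshold took only 58 of 14361 and 37 of 14284 marked genes of any kind. Hindbrain tissue in the dissected midbrain cannot be told apart from other origins, as 8 of 12 genes of paralog groups 1 to 4 and 6 of 12 of groups 10 to 13 were marked (Fisher's exact p = 0.680), too few to decide. No biological explanation was tested, as the series has 1 group.

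The third pattern is the strong peaks over 5000 bp from every annotated TSS, 42 peaks with a signal of at least 42.1, the median of peaks at TSSs. TSSs missing from the annotation used are a candidate explanation, since 57.1% of them lay within 1000 bp of a RefSeq TSS, against 11.0% of the other 4257 distant peaks. Among the 5 strongest, the peaks near Arhgap32, Fcgr4, Otub1 and Dtna were of this kind and the one inside Ldb3 was not. Repeated sequence stays open. The upper quartile of repeat-masked bases was 14.7%, against 15% at TSS peaks. The median was 10.6%, against 10.3% at TSS peaks and 9.25% at the other distant peaks, and missed the stricter bound set first. The share of masked bases thus differed little between classes of called peaks, and repeated sequence that is not masked was not measured. The test can therefore not decide. Strong distant peaks without a RefSeq TSS nearby remain without an explanation, and no biological one was tested.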
